A study of Mus musculus with 16 samples.

How the data were processed

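The series holds 16 RNA-seq libraries of mouse embryonic fibroblasts from 4 cell lines, 2 wildtype (Zac+/+) and 2 Zac1 mutant (Zac+/-), each harvested at days 2, 8, 10 and 12 in vitro. Groups, days and replicate numbers were taken from the labels, which also give a letter, I for both replicate 1 lines and L for both replicate 2 lines. The title code of the mutant lines was not expanded, and what the letters mark was not given in the sources used here.

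The deposited table holds whole-number counts of reads per gene, not normalized, for 23100 genes named by symbol and NCBI gene ID. Per the labels' protocols, stranded libraries were prepared from DNase-treated RNA. Per the submitters' processing notes, the tools were bcl2fastq 2.18, TopHat2 2.1.1, Bowtie2 2.2.9 and HTSeq 0.6.1p1 with the mouse build mm9. The gene annotation and the strand setting of the counting were not given in the sources used here, so genes that overlap on opposite strands, and genes with near-identical copies, are uncertain. The reference at hand was another build (GRCm38.p6), so no coordinates are given, and it was used only to look up whether a gene lies on X or Y. No row without a gene name was found, and 0 columns belonged to other samples.

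The total count per library was 28079241 to 61039793, and a count of 3 corresponds to 0.0491 to 0.107 CPM. Depth was lowest in mutant replicate 1 at day 2 (28079241) and highest in wildtype replicate 2 at day 2 (61039793). Libraries of one group differed by far more than counting error (chi-square per degree of freedom 34.1 to 73.1), so none was a copy of another. Intervals and bounds from counts cover counting error only. No gene took more than 2.43% of a library.

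CPM values were computed from the deposited counts with TMM scaling. The counts of days 8, 10 and 12 of each line were summed, since these are repeat harvests of one line, giving 8 summed libraries in 4 groups of genotype and state. Genes were kept by edgeR's filterByExpr (15740 genes), and edgeR's quasi-likelihood test (R 4.3.3, edgeR 4.0.16, TMM, robust, 4 residual degrees of freedom) gave log2 fold changes and p, Benjamini-Hochberg adjusted and called under 0.05. Standard errors (SE) were derived from this test, as the absolute log2 fold change over the square root of its F statistic. The contrasts were mutant minus wildtype in each state, their difference, and quiescent minus proliferative in each genotype. The main summed fit had no term for the line, so the day 2 library and the quiescent sum of a line counted as independent. Comparisons within a day, and of day 12 with day 8, used the 16 libraries in 8 groups (15439 genes, 8 residual degrees of freedom), which counts repeat harvests of a line as independent. An exact permutation test of 2 lines against 2 cannot give a two-sided p under 0.333, so calls rest on the spread shared across genes.

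A total of 44 gene lists and the rules below were fixed before the data were examined. The series title speaks of genes of the extracellular matrix and of the network of imprinted genes, so lists of both were included beside lists for the cell cycle, signalling, metabolism and other cell types. Of the lists, 42 had at least 4 tested genes. Erythroid markers (2 tested) and mitochondrially encoded genes (0) were not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 42 lists within a comparison, and beside it with an estimated correlation and with fry. Median log2 values of lists are over fitted values. With genes at 0 counts set to their bounds, the median of a called list moved at most from 0.15 to 0.18 (proteoglycans, genotype in proliferation).

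The genes named were Plagl1, the 12 rising and 12 falling genes with the largest change for genotype at quiescence, and 8 of each for the other comparisons, among called genes whose lines did not overlap between groups, with a mean of at least 5 CPM in a group and leaving out predicted genes. Up to 4 members with the smallest p in each list, and the 5 smallest p where a comparison had no call, were also named. Other genes are named to illustrate a list or a line and were chosen after their values were seen. Some genes that met these rules are not reported here. A fold against a group with 0 counts is given as a lower bound from 3 counts over the group, and 1 to 3 counts as a ratio with a 95% counting interval.

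The same cell line was harvested in every state and day, so the numbers pair samples in the comparisons of states and days by design. The consensus correlation of harvests of one line was 0.0911 (limma's duplicateCorrelation). Blocking on the line changed the counts of genes by more than 1.5 times for day 12 against day 8. Alternatives were another normalization (RLE, upper quartile), DESeq2 1.42.0, limma-voom with the line as a random block, other filters on low counts, a test against a fold change of 1.5, leaving out each line or quiescent day, the libraries of a comparison alone, and blocks. The tests were checked on simulated data drawn from the real means and fitted dispersions with 200 changed genes. For genotype at quiescence (15482 genes) 25.4% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, and 12 of 140 calls were false. For genotype in proliferation (15480 genes) the shares were 25.4%, 77.6% and 90.9% with 14 of 144 false calls, for the interaction (15472 genes) 2.99%, 34.3% and 77.3% with 5 of 81, and for day 8 (15223 genes) 17.9%, 73.1% and 95.5% with 6 of 130. False calls in the quiescent, proliferative and interaction simulations were above the nominal 5%. A planted list raised by 0.2 on the log2 scale had a camera p of 0.00237 in the quiescent simulation and an unchanged list 0.443, with genes simulated as independent. The state and day 12 comparisons were not simulated in a way that counts false calls.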

Results

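RNA was sequenced from mouse embryonic fibroblasts, cultured connective tissue cells taken from embryos, of the C57BL/6 strain. The cells were wildtype (Zac+/+) or carried a mutation of Zac1 (Zac+/-), the gene now called Plagl1, which encodes a zinc finger transcription factor and is an imprinted gene expressed from the paternal copy. There were 4 cell lines, 2 per genotype, and each was harvested at day 2 in vitro, called proliferative in the labels, and at days 8, 10 and 12, called quiescent. This gave 16 libraries in 8 groups of genotype and day, with 2 lines in each group. Read counts were given for 23100 genes, and the total count per library ran from 28079241 to 61039793. The cell line was taken as the replicate, so the 3 quiescent harvests of a line were summed before genotypes or states were compared. The day 2 library and the quiescent sum of a line were still counted as independent in the fit.

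Plagl1 (NCBI gene 22634) was measured first, as a check of the labels. In wildtype cells its level rose from 41.6 ± 5.47 CPM (counts scaled to the library total) at day 2 to 146 ± 26.4 at day 8, 188 ± 33.1 at day 10 and 218 ± 18.7 at day 12 (mean ± SD, n = 2 lines). In mutant cells the levels were 8.37 ± 1.09, 52.0 ± 5.18, 46.1 ± 7.95 and 53.8 ± 9.23 CPM, which is 20.1%, 35.5%, 24.5% and 24.7% of wildtype. In the summed libraries Plagl1 was lower in mutant than in wildtype cells by a log2 fold change of -1.88 (SE 0.15, edgeR adjusted p = 0.00297) at quiescence and -2.31 (SE 0.16, edgeR adjusted p = 8.50e-04) in proliferation. Between proliferation and quiescence Plagl1 rose 4.44-fold in wildtype (log2 2.15, SE 0.15, adjusted p = 4.07e-06) and 6.00-fold in mutant cells (log2 2.58, SE 0.16, adjusted p = 3.59e-06). The difference of these 2 log2 changes was 0.43 (SE 0.21) and did not pass the test (edgeR adjusted p = 1.00). Which part of the gene the mutation removes was not given in the sources used here, so the remaining counts cannot be assigned to an intact or an altered transcript.

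**Figure D1:**
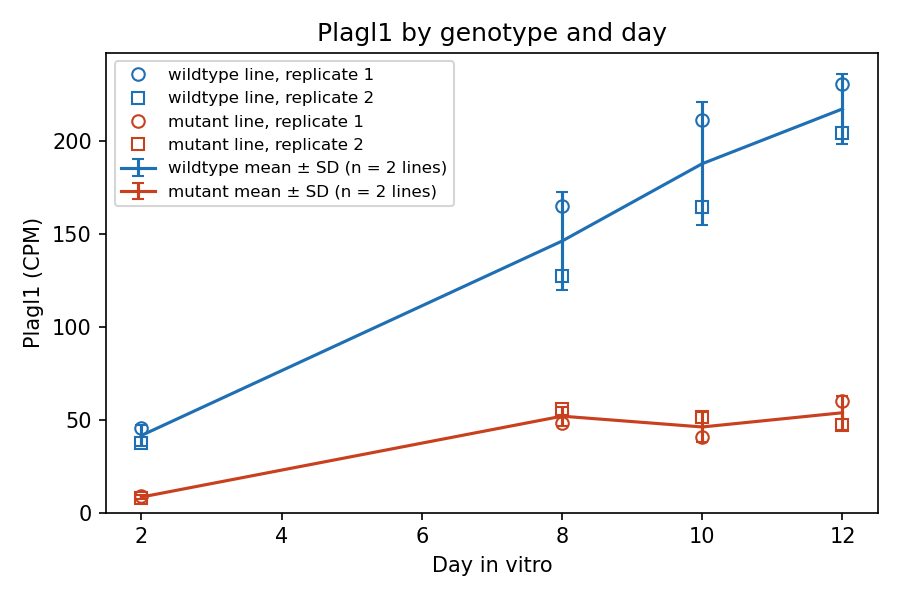
Plagl1 level in CPM (vertical axis, starting at 0) against day in vitro (horizontal axis) for wildtype and mutant lines, with 1 point per cell line, and means of 2 lines joined with SD bars. The wildtype mean rises from 41.6 at day 2 to 218 at day 12, and the mutant mean stays between 8.37 and 53.8.

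The comparison of genotypes at quiescence asked which genes, among them extracellular matrix and imprinted genes, depend on Zac1 in resting fibroblasts. Plagl1 itself was the 1 gene of 15740 that passed the test, and it fell. The imprinted genes lay a little lower in mutant cells as a group. In the imprinted gene network, a fixed list of coexpressed growth-related imprinted genes, 10 of 15 members were lower (median log2 -0.05), and of the other imprinted genes 28 of 38 were lower (median -0.08). Members with a small unadjusted p included the growth inhibitor Cdkn1c (62.4 ± 13.0 CPM in wildtype and 41.6 ± 9.74 in mutant, log2 -0.59, SE 0.18), the noncoding RNA Meg3 (log2 -0.45, SE 0.18) and the zinc finger gene Zim1 (-0.44, SE 0.18), none of which passed (edgeR adjusted p = 1.00 for each). Among matrix genes, Col1a2 and Col1a1, the chains of type I collagen, had log2 values of 0.20 (SE 0.11) and 0.18 (SE 0.12), and 9 of 11 fibrillar collagens were higher (median 0.18).

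Set against all other genes with camera's preset correlation, 15 of 42 tested lists were called at quiescence, 10 of them higher and 5 lower in mutant cells. These numbers depended on single lines, with 12 higher and 2 lower without wildtype replicate 1, 6 and 9 without wildtype replicate 2, 9 and 9 without mutant replicate 1 and 9 and 6 without mutant replicate 2. No member of these 15 lists passed over all genes, and 0 passed when adjusted over the list alone. Cholesterol synthesis genes such as Idi1 and Fdps were higher for 18 of 19 members (median 0.14, camera adjusted p = 1.65e-05, adjusted p = 0.532 with an estimated correlation). Glycolysis genes were higher for 16 of 17 (median 0.12, camera adjusted p = 4.88e-05, adjusted p = 0.532 with an estimated correlation), as were 16 of 17 endoplasmic reticulum stress genes (median 0.10, same adjusted p values). The other imprinted genes (camera adjusted p = 5.16e-04) and the imprinted gene network (adjusted p = 0.00309) were lower, each with adjusted p = 0.418 with an estimated correlation. The estimated correlation of the network was -0.0112, below the preset 0.01, and its unadjusted camera p still went from 4.41e-04 to 0.0199. The loss of its call therefore did not come from a higher correlation between its members. The setting thus raised p apart from correlation, and lost calls of other lists cannot be put down to correlation alone. Fibrillar collagens had an adjusted p of 0.0293 in camera (adjusted p = 0.532 with an estimated correlation). Cartilage marker genes were higher for 10 of 13 members (median 0.88, adjusted p = 0.00852, adjusted p = 0.726 with an estimated correlation), and this depended on single lines. In mutant replicate 2 Acan, the cartilage proteoglycan core protein, stood at 37.4 CPM against 2.11, 2.45 and 6.13 in the other 3 lines. Without that line the list was lower in mutant cells (camera adjusted p = 7.17e-07), and without wildtype replicate 1 it was not called (adjusted p = 0.552). Bone-forming cell markers were lower for 9 of 9 members (median -0.25) and the anterior Hox genes for 12 of 14 (median -0.18), with camera adjusted p of 0.00496 and 0.00221 (adjusted p = 0.532 and adjusted p = 0.586 with an estimated correlation). The bone list also depended on single lines and was not called without mutant replicate 1 (adjusted p = 0.839) or wildtype replicate 1 (adjusted p = 0.240). Its summed level was 69.5 and 61.9 CPM in wildtype replicates 1 and 2 and 51.6 and 70.7 in mutant replicates 1 and 2. Macrophage and blood markers lay higher for 15 of 15 members (median 0.54) without being called (adjusted p = 0.506), and differed more between lines of one genotype, as given below. The other called lists were myofibroblast, TGF-beta target, G2/M, S phase and ribosomal protein genes, higher by medians of 0.06 to 0.12, and Wnt pathway genes (median -0.14), with adjusted p from 0.532 to 0.807 with an estimated correlation. Housekeeping genes were also higher, for 14 of 14 members (median 0.05), without being called (camera adjusted p = 0.139). Fry, which does not compare a list with other genes, called 0 lists, and camera with an estimated correlation called 0. Other splits of the lines also gave calls with the preset correlation. Setting both replicate 2 lines against both replicate 1 lines gave 16 lists. Setting mutant replicate 1 and wildtype replicate 2 against the other lines gave 10. Anterior Hox genes were lower in both splits (median -0.33 in each, camera adjusted p = 0.00493 and 1.53e-05). Wildtype replicate 1 was on the higher side in both of these splits and in the genotype split. The genotype shift of the anterior Hox genes therefore cannot be told apart from a high level in that line alone. In proliferation these splits gave 2 lists each, against 14 for genotype.

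At quiescence 76 genes had an unadjusted p under 0.05, against 787 by chance, and DESeq2 and limma-voom also called 1 gene each. Leaving out wildtype replicate 2 gave 4 genes (Plagl1, Aqp5, Esm1 and Tbx4), and a fit of the 4 quiescent sums alone called 0.

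In proliferating cells Plagl1 was again the 1 gene called between genotypes, lower in mutant cells. Col3a1, the chain of type III collagen, was at 366 ± 29.5 CPM in wildtype and 524 ± 37.6 in mutant cells (log2 0.52, SE 0.13). It did not pass over all genes (edgeR adjusted p = 1.00) and was the 1 fibrillar collagen that passed when adjusted over the list alone. Islr, a secreted leucine-rich repeat protein (log2 1.35, SE 0.24), and Cpxm1, a carboxypeptidase-like protein (0.74, SE 0.13), also missed the threshold (edgeR adjusted p = 1.00 for both). They were chosen after their values were seen.

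Camera with the preset correlation called 14 of 42 lists in proliferation, 11 higher and 3 lower, and with an estimated correlation it called 0. Without wildtype replicate 1 it called 3, all higher, so none of the 3 lower lists was kept, and without wildtype replicate 2 it called 10 higher and 4 lower. The numbers were 6 and 3 without mutant replicate 1 and 5 and 5 without mutant replicate 2. Fibrillar collagens were higher for 10 of 11 members (median 0.19, camera adjusted p = 8.84e-05) and other collagens for 16 of 18 (median 0.37, adjusted p = 1.65e-04), both with adjusted p = 0.404 with an estimated correlation. Matrix proteases and inhibitors (21 of 25 higher), elastic fibre and microfibril genes (17 of 18) and pericyte markers (7 of 8) had camera adjusted p of 0.00177, 0.00311 and 0.00468, again with adjusted p = 0.404 with an estimated correlation. Ribosomal protein genes were lower for 28 of 28 members (median -0.16, camera adjusted p = 1.09e-08, adjusted p = 0.472 with an estimated correlation). G2/M genes were lower for 23 of 25 (median -0.14, adjusted p = 5.79e-05, adjusted p = 0.404 with an estimated correlation) and S phase genes for 18 of 25 (median -0.09, adjusted p = 0.0205, adjusted p = 0.472 with an estimated correlation). Proteoglycans, basement membrane, integrin, Wnt pathway and IGF axis genes were higher by medians of 0.11 to 0.15 (camera adjusted p from 0.0205 to 0.0439, and adjusted p from 0.472 to 0.633 with an estimated correlation). Matrix glycoproteins were called higher (median 0.12, adjusted p = 0.0250, adjusted p = 0.404 with an estimated correlation), while their mean was -0.05. Their member Thbs4, a thrombospondin, had 0 counts in proliferating mutant cells, and its fitted value enters the mean. Matrix crosslinking enzymes were not called (adjusted p = 0.0967). Housekeeping genes were lower for 11 of 14 (median -0.07) and were not called either (camera adjusted p = 0.186). Apart from Col3a1, no member of these lists passed when adjusted over the list alone.

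In proliferation 451 genes had an unadjusted p under 0.05, against 787 by chance. DESeq2 called 3 genes (Plagl1, Islr and Cpxm1), as did edgeR without mutant replicate 1 (Plagl1, Clec11a and Islr).

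Whether the genotype difference itself changed between states was tested as an interaction. No gene passed in edgeR (0 of 15740, with 265 at an unadjusted p under 0.05), DESeq2 called 1 (Islr) and limma-voom 0. Islr was 1.35 higher on the log2 scale in proliferating mutant cells and stood at -0.23 at quiescence (difference -1.59, SE 0.29, edgeR adjusted p = 1.00). Among lists, ribosomal protein genes moved from a median of -0.16 in proliferation to 0.06 at quiescence (camera adjusted p = 2.92e-09, adjusted p = 0.529 with an estimated correlation) and G2/M genes from -0.14 to 0.07 (adjusted p = 2.32e-06, adjusted p = 0.475 with an estimated correlation). Housekeeping genes moved the same way, from -0.07 to 0.05, without being called (camera adjusted p = 0.0633). In all, 10 lists were called with the preset correlation and 0 with an estimated one, and fry called 0 here and in proliferation.

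By day, Plagl1 was the 1 gene called between genotypes at each quiescent day. Its log2 fold change was -1.49 (SE 0.19, edgeR adjusted p = 0.0248) at day 8, -2.03 (SE 0.19, adjusted p = 8.24e-04) at day 10 and -2.02 (SE 0.19, adjusted p = 9.00e-04) at day 12. The counts at an unadjusted p under 0.05 were 276, 1507 and 227 of 15439 genes, against 772 by chance. DESeq2 called 15 genes at day 10, among them the imprinted Zim1 and Rian, which were lower in mutant cells, and the kinase Nuak2, which was higher, and it called 1 gene at days 8 and 12. These fits counted repeat harvests of 4 lines as independent. Plagl1 was not called at day 8 when any 1 line was left out, at day 10 without wildtype replicate 1, or at day 12 without wildtype replicate 1 or mutant replicate 2. Without mutant replicate 1 the day 10 count was 51, and without wildtype replicate 2 it was 4 (Plagl1, Aqp5, Tbx4 and Mab21l2).

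The comparison of states asked how the cells changed from proliferation to quiescence. In wildtype cells the cell cycle genes fell throughout, with 25 of 25 G2/M genes (median log2 -2.20) and 25 of 25 S phase genes (median -2.04) lower. The ribonucleotide reductase subunit Rrm2 went from 307 ± 8.91 to 39.9 ± 0.90 CPM (log2 -2.94, SE 0.11, edgeR adjusted p = 3.16e-07, n = 2 lines), and the mitotic kinase Aurka from 100.5 to 15.6 CPM. Col3a1 went from 366 ± 29.5 to 7728 ± 1008 CPM (21.1-fold, log2 4.40, SE 0.14, adjusted p = 2.09e-07), the small proteoglycan decorin, Dcn, from 14.2 ± 3.80 to 305 ± 2.96 (21.7-fold), and the growth factor Igf1 from 5.55 ± 0.10 to 215 ± 4.95 (38.7-fold).

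By list, 17 of 22 proteoglycans rose and none fell (median 2.77), among them Lum (log2 6.53, SE 0.38), Fmod (5.16, SE 0.26) and Aspn (4.90, SE 0.26). Of the fibrillar collagens 8 of 11 rose (median 1.42), of the other collagens 13 of 18 rose and 1 fell (median 2.11), and of the matrix glycoproteins 21 of 29 rose and 2 fell (median 1.31), including the thrombospondin Thbs2 (6.92-fold). In the imprinted gene network 9 of 15 genes rose and 2 fell (median 1.39). Mest rose 41.8-fold, H19 9.99-fold, Peg3 4.50-fold and Cdkn1c 2.62-fold, while Gatm and Slc38a4 fell (log2 -2.40 and -1.17). Interferon response genes rose for 20 of 25 members (median 2.39), as Isg15 did (log2 4.04, SE 0.26). Matrix proteases and inhibitors rose for 18 of 25 and fell for 4, with Mmp2, a gelatinase, up 4.97-fold. IGF axis genes rose for 12 of 20 and fell for 6, with Igfbp5 up 32.9-fold. Elastic fibre genes rose for 11 of 18 and fell for 1, Wnt pathway genes for 11 and 2 of 24, growth arrest genes for 10 and 1 of 16, and basement membrane genes for 9 and 1 of 20. Ribosomal protein genes fell for 27 of 28 (median -0.65), cholesterol synthesis genes for 15 of 19, glycolysis genes for 11 of 17 with 2 that rose, and housekeeping genes for 9 of 14 with 1 that rose. Adjusted over the list alone, the counts were 25 and 25 down for the cell cycle lists, 18 up for proteoglycans, 9 up for fibrillar collagens, 14 up and 1 down for other collagens, 21 up for interferon response genes and 9 up and 2 down for the imprinted gene network.

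These 18 lists were called by camera with the preset correlation, with adjusted p from 1.29e-46 (G2/M) to 0.0282 (glycolysis). Fry, which does not compare a list with other genes, called 29 of 42 lists, with 7486 of 15740 genes called. In camera with an estimated correlation 3 of the 18 remained called, the G2/M, S phase and matrix glycoprotein lists (adjusted p = 0.0294 each). The others had adjusted p = 0.0828 with an estimated correlation for proteoglycans, both collagen lists and the imprinted gene network, 0.102 for matrix proteases, 0.121 for elastic fibre, 0.158 for IGF axis, 0.178 for Wnt and 0.206 for interferon response genes, 0.260 for cholesterol synthesis, 0.445 for basement membrane, growth arrest, glycolysis and housekeeping genes, and 0.450 for ribosomal proteins. The inhibitors of cyclin-dependent kinases and pocket proteins rose for 10 of 14 members and fell for 1 without the list being called (camera adjusted p = 0.0570, adjusted p = 0.294 with an estimated correlation). Integrins rose for 8 of 16 and fell for 5, and matrix crosslinking enzymes for 7 and 4 of 18, and neither list was called (camera adjusted p = 0.217 and 0.300). Macrophage markers, whose levels differed between the lines, had a median of 1.41 with 0 of 15 called (camera adjusted p = 0.512). Bone-forming cell markers rose for 5 of 9 (median 2.80), cartilage markers for 5 of 13 (2.26) and pericyte markers for 5 of 8 with 2 that fell (1.41). Epithelial markers rose for 2 and fell for 4 of 10 (median -1.09). None of these lists was called (camera adjusted p = 0.0558, 0.0973, 0.158 and 0.0558).

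The genes with the largest changes in wildtype cells that met the rule for naming included Cxcl15, a chemokine, at least 285-fold higher at quiescence, Cldn19, a claudin, at least 226-fold (at 2.55 and 11.4 CPM in the quiescent lines, so that the bound depends on the line), and Iigp1, an interferon-inducible GTPase, at least 175-fold, all with 0 counts in proliferation and bounds taken at 3 counts over the group. Scara5, a scavenger receptor, had 1 count in proliferation and a ratio of 1891 (95% counting interval 339 to 74707). Egfl6, a secreted matrix protein, rose by 8.02 on the log2 scale (SE 0.35, edgeR adjusted p = 8.35e-07). Those that fell included U90926 (log2 -6.33, SE 0.42), the hyaluronan synthase Has2 (-3.64, SE 0.38) and the phosphatase Dusp9 (-3.87, SE 0.22). In total 7486 of 15740 genes were called, 3756 up and 3730 down. The count was 4185 without wildtype replicate 1, 4380 without wildtype replicate 2, and 3452 when tested against a fold change of 1.5.

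**Figure D2:**
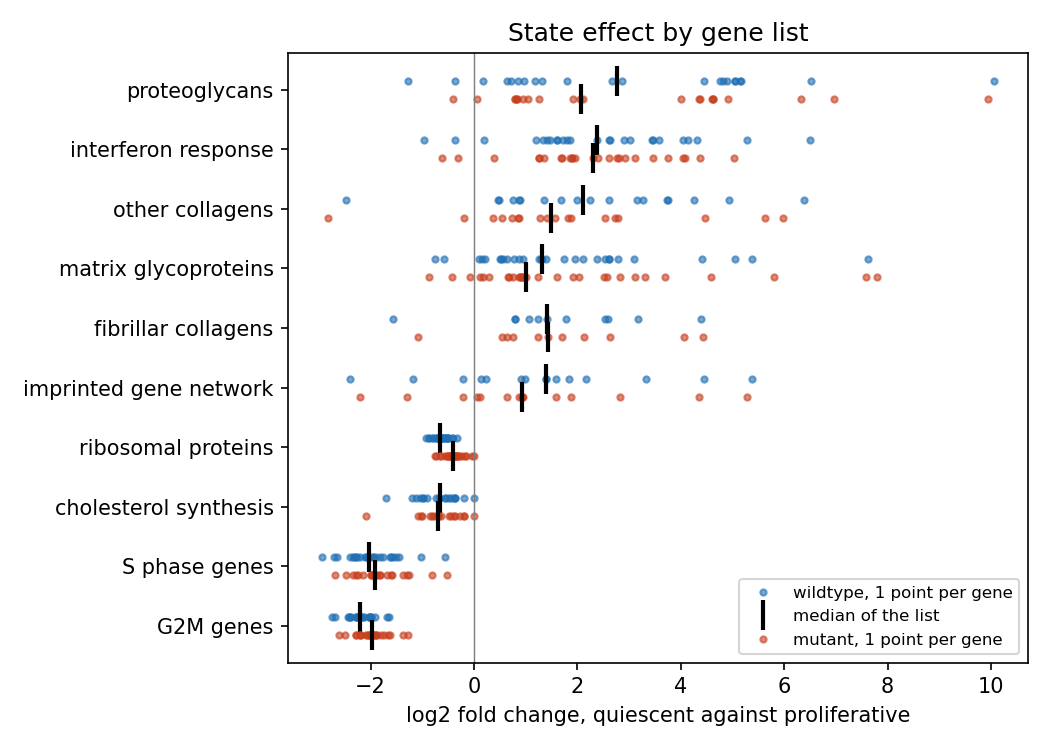
Fitted log2 fold change from proliferation to quiescence (horizontal axis) for the genes of 10 fixed lists (vertical axis), with 1 point per gene for wildtype and mutant cells and a bar at each list's median. The G2/M and S phase genes lie below 0 in both genotypes (medians from -2.20 to -1.92) and the proteoglycan medians are 2.77 and 2.08, and points of genes with few counts in proliferation depend on the fit's prior count.

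In mutant cells the same groups moved. The G2/M genes fell for 25 of 25 (median -1.97), as did 25 of 25 S phase genes (median -1.92), with Rrm2 going from 267 ± 11.1 to 41.2 ± 2.53 CPM (log2 -2.70, SE 0.10, edgeR adjusted p = 7.83e-07, n = 2 lines). Col3a1 rose 16.6-fold from 524 ± 37.6 to 8710.2 ± 362 CPM, Igf1 27.8-fold and Dcn 20.5-fold. Proteoglycans rose for 17 of 22 (median 2.08), fibrillar collagens for 8 of 11 (1.44), other collagens for 12 of 18 with 1 that fell (1.49), matrix glycoproteins for 20 of 29 with 2 that fell (1.00) and interferon response genes for 21 of 25 (2.30). In the imprinted gene network 9 of 15 rose and 2 fell (median 0.92), Cdkn1c rising 1.90-fold and Peg3 3.67-fold. Ribosomal protein genes fell for 20 of 28 (median -0.41). The largest rises that met the naming rule included Steap4, a metalloreductase (at least 348-fold, at 8.58 and 17.0 CPM in the quiescent lines), Scrg1 (at least 154-fold) and Abi3bp (log2 7.29, SE 0.20), and the largest falls Lce1h and U90926 (log2 -5.25 and -5.08).

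Camera called 20 lists in mutant cells with the preset correlation, the same 18 and 2 more. Epithelial markers fell for 6 of 10 and rose for 2 (camera adjusted p = 0.0115, adjusted p = 0.296 with an estimated correlation) and cartilage markers rose for 5 of 13 (adjusted p = 0.0485, adjusted p = 0.646 with an estimated correlation). The cartilage list was not called without mutant replicate 2 (adjusted p = 0.108), where its summed level went from 421 to 647 CPM, against 183 to 182 in mutant replicate 1. The G2/M and S phase lists (adjusted p = 0.0236 each) and matrix glycoproteins (adjusted p = 0.0277) stayed called with an estimated correlation, while proteoglycans had adjusted p = 0.0731, the imprinted gene network adjusted p = 0.127 and interferon response genes adjusted p = 0.217 with an estimated correlation. Among the rest the adjusted p with an estimated correlation was 0.120 for fibrillar collagens, 0.138 for other collagens, elastic fibre genes and matrix proteases, 0.147 for IGF axis, 0.228 for Wnt and 0.283 for cholesterol synthesis genes, 0.427 for growth arrest, 0.526 for housekeeping and glycolysis, 0.557 for basement membrane and 0.603 for ribosomal protein genes. In total 6633 genes were called, 3325 up and 3308 down. Of these, 6042 were also called in wildtype, all in the same direction (2954 up and 3088 down, against 793 and 784 for independent lists). Across the tested genes, which are not independent replicates, the state changes of the genotypes correlated with r = 0.83. Over the 9673 genes of at least 10 CPM in 2 summed libraries, r was 0.98. When tested against a fold change of 1.5 the count was 2703. Fry called 30 of 42 lists in mutant cells.

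The later quiescent days were compared to see whether the resting cells still changed. From day 8 to day 12 mitotic genes kept falling. In wildtype cells 21 of 25 G2/M genes fell (median log2 -1.01; 25 adjusted over the list alone), with Birc5, the inhibitor of apoptosis survivin, at -1.25 (SE 0.13, edgeR adjusted p = 0.00119) and the proliferation marker Mki67 at -1.07 (SE 0.18). In mutant cells 23 of 25 fell (median -1.07; 25 adjusted over the list alone), with Birc5 at -1.36 (SE 0.13, adjusted p = 5.32e-04). S phase genes fell for 6 of 25 in wildtype and 12 of 25 in mutant cells (22 and 21 adjusted over the list alone). Genes that rose in both genotypes included Dcn (log2 1.34 and 1.26), Col3a1 (0.77 and 0.75), the Wnt regulator Sfrp2 (2.83 and 2.41) and Txnip, a thioredoxin inhibitor (0.98 and 0.99). Igf1 rose in wildtype (1.15, SE 0.16, adjusted p = 0.00321) and had 0.46 (SE 0.15, adjusted p = 0.306) in mutant cells, a difference that was not tested. Markers of other cell types had medians as large with 0 genes called, at 1.25 in wildtype and 1.27 in mutant cells for macrophage and 1.18 and 1.71 for cartilage markers.

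In wildtype cells 126 genes were called between days 12 and 8 (27 up, 99 down) and in mutant cells 168 (33 up, 135 down), of which 105 were shared, all in the same direction. With the line as a block, since each line was harvested on both days, the counts were 304 (148 up, 156 down) and 319 (139 up, 180 down), and DESeq2 called 306 and 357. The fits counted harvests as independent, and the counts moved when a line was left out: in wildtype to 1 and 0 without wildtype replicates 1 and 2 and to 192 without either mutant line, and in mutant cells to 63, 74, 47 and 29 without wildtype replicates 1 and 2 and mutant replicates 1 and 2.

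The lines of one genotype also differed from each other. The first principal component held 57.8% of the variance and separated day 2 from the later days. The second held 8.81%, and its ends were held by the mutant lines, with replicate 1 between 18.1 and 41.2 and replicate 2 between -49.3 and -11.5. Macrophage transcripts differed between lines of each genotype: the complement gene C1qa stood at 4.13 and 14.6 CPM in wildtype replicates 1 and 2 and at 25.2 and 2.85 in mutant replicates 1 and 2, summed over quiescent days, and Lyz2, lysozyme, at 26.9, 95.1, 156 and 17.3. Every line held both the female transcript Xist and the Y-linked Ddx3y, with Ddx3y at the quiescent days highest in mutant replicate 2 (82.8 to 123 CPM) and lowest in mutant replicate 1 (11.1 to 23.0 CPM). Tbx4, a hindlimb transcription factor, was lower in wildtype replicate 1, where it stood at 10.4 CPM against 37.7, 34.8 and 36.0 in wildtype replicate 2 and mutant replicates 1 and 2. With 2 lines per genotype, these differences lie within the spread that the genotype tests use.

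**Figure D3:**
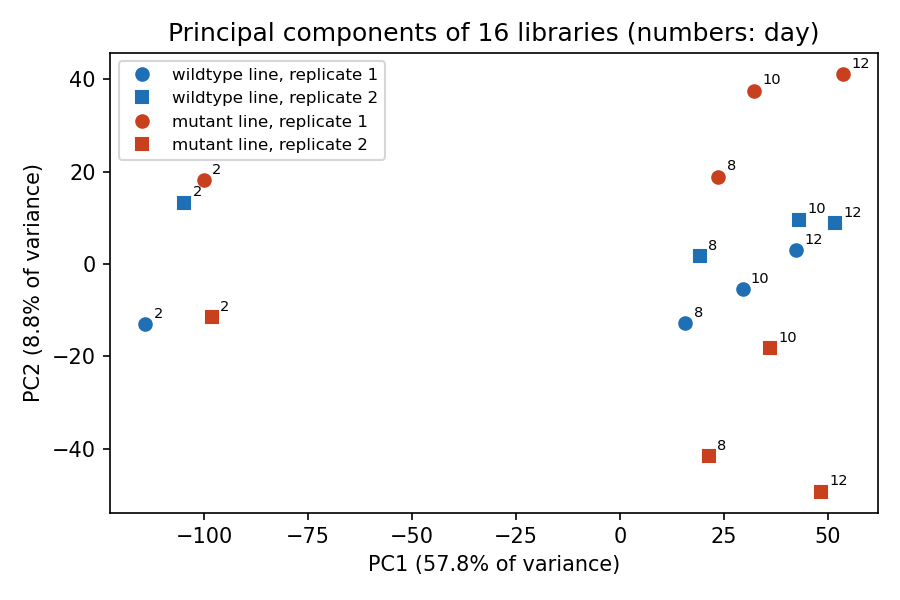
Scores of the 16 libraries on principal component 1 (57.8% of the variance, horizontal axis) and component 2 (8.81%, vertical axis) of log2 CPM, with 1 point per library, marked by genotype, replicate and day. Day 2 libraries lie at negative scores on component 1 and the other days at positive ones, and the mutant lines lie apart on component 2.

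**Figure D4:**
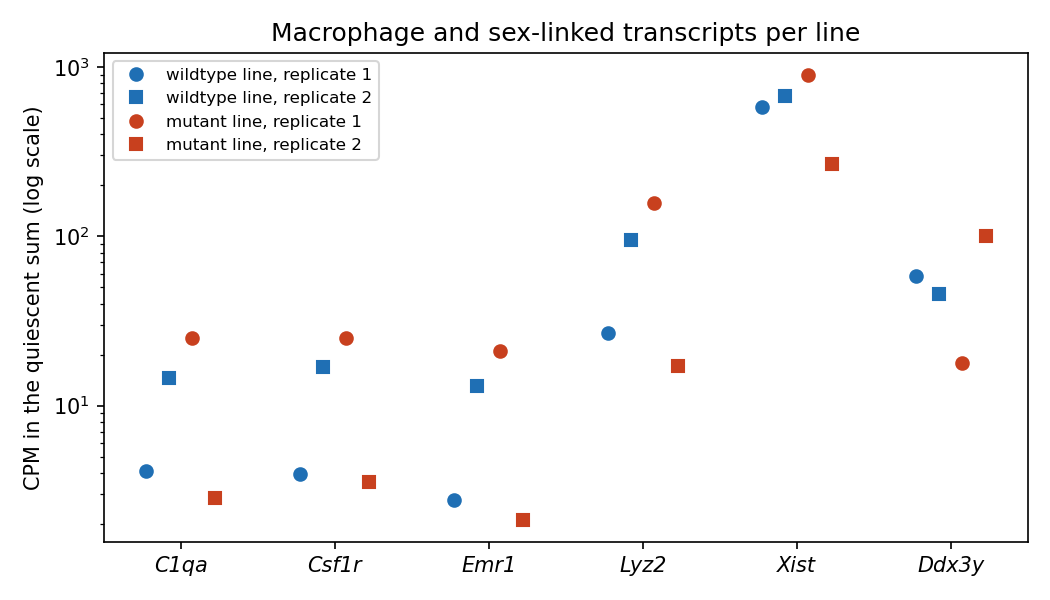
CPM on a log scale (vertical axis) of 4 macrophage genes, Xist and Ddx3y (horizontal axis) in the quiescent sum of each line, with 1 point per line. For C1qa, mutant replicate 1 and wildtype replicate 2 stand at 25.2 and 14.6 and the other lines at 4.13 and 2.85.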

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

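Among the tests here, those of macrophage content, of sex-linked genes and of a shared batch, and the counts over other splits, were chosen after the results were seen. So were the comparison of depth with the macrophage level and the folds after thinning, while the thinnings to 72056005 counts and at day 2 were added after the first thinning was seen, with their bounds set before they were run. Each group held 2 libraries, so standing apart from a group was not tested for single libraries.

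The genotype effect differed between states for 10 gene lists by camera's test of the interaction with the preset correlation, and for 0 with an estimated correlation (smallest adjusted p = 0.475). Mutant minus wildtype was more positive at quiescence than in proliferation for ribosomal protein genes (28 of 28 members, adjusted p = 2.92e-09), G2/M genes (24 of 25, adjusted p = 2.32e-06) and S phase genes (21 of 25, adjusted p = 0.00176). It was more negative at quiescence for matrix proteases and inhibitors (20 of 25, adjusted p = 0.00129), other collagens (15 of 18, adjusted p = 0.00187), Wnt pathway genes (21 of 24, adjusted p = 0.00258), bone-forming cell markers (8 of 9, adjusted p = 0.00400), the imprinted gene network (13 of 15, adjusted p = 0.0124), pericyte markers (6 of 8, adjusted p = 0.0267) and anterior Hox genes (13 of 14, adjusted p = 0.0300).

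Macrophage genes were higher in mutant replicate 1 and wildtype replicate 2 than in the other 2 lines. With the lines split that way, 24 genes were called at quiescence and 21 in proliferation, all higher, among them Emr1, Csf1r, C1qa, Itgam and Cx3cr1. A difference in depth is argued against. At quiescence depth differed between the lines by at most 1.14-fold, and the macrophage list's summed level by at least 3.30-fold between a higher and another line. The order of depth there did go with the split, at 164614246 and 149665008 counts in the 2 higher lines and 147127361 and 144112010 in the others. At day 2 the higher lines had the lowest and the highest depth (28079241 and 61039793 counts), and the level differed by at least 4.25-fold against 2.17-fold for depth. Thinning every quiescent sum to the lowest total (144112010) took away few counts and was no test. With the 2 higher sums thinned to 72056005, below the others, 23 of the 24 genes were kept. The median of all 24 was 2.49 (quartiles 2.37 and 2.67) against 2.48 before. At day 2, thinned to the lowest total, 12 of the 21 were kept. The 9 lost had a median of 3.45 before and 3.44 after. The median of their single-gene SEs went from 0.47 to 0.53, so the calls ended with a larger error and not a smaller fold. Both thinnings missed bounds set beforehand, on how many other genes moved and how many calls were kept, and the number of calls falls with fewer reads whatever the cause. A different share of female and male cells stays open. While 0 of the 24 genes lie on X or Y (GRCm38.p6), the sex-linked list, made of Xist and 4 Y-linked genes, differed along the same split at quiescence (median -1.32, camera adjusted p = 4.09e-07), and an indirect effect was not tested. Macrophages present in different numbers in the cultures stay open as well. All 15 tested genes of the macrophage list lay over 0.5 on the log2 scale at quiescence (median 2.49, quartiles 2.30 and 2.55), but this restates the pattern, which was named from genes of that kind. The macrophage list's summed level was 70.2 and 231 CPM in wildtype replicates 1 and 2 and 385 and 49.3 in mutant replicates 1 and 2, led by Lyz2 at 156 CPM in mutant replicate 1. As genotype is crossed with this split, it adds to the spread within each genotype.

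More genes were called between the lettered pairs of lines than between genotypes. Comparing both replicate 2 lines with both replicate 1 lines gave 1004 genes in proliferation and 82 at quiescence, against 1 and 1 for genotype, which points to a structure of the samples. Depth differed between these pairs at day 2, but with all 4 libraries thinned to 28079241 counts 921 genes were called, 820 of them shared with the 1004, which argues against depth as the whole cause. A batch or litter shared by the lines of one letter cannot be told apart from other differences between the lines, since the labels give neither, and the 1004 calls stay open. Of the 3 splits of the 4 lines, 1 is the genotype split itself. The other 2 each gave more genes than it did, 82 and 24 at quiescence and 1004 and 21 in proliferation. Splits this few cannot give a share under 0.05.

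Imprinted genes lay lower in quiescent mutant lines, with camera adjusted p of 0.00309 and 5.16e-04 for the imprinted gene network and the other imprinted genes (adjusted p = 0.418 with an estimated correlation for each). In the other 2 splits of the lines the smallest adjusted p of these lists was 0.179. A rule written beforehand took such a value to argue against differences between lines unrelated to genotype, but it was too weak. The crossed split gave medians of -0.06 and -0.08 against -0.05 and -0.08 for genotype, so median shifts of that size arose without genotype. By camera the splits were less alike. Its unadjusted p was 4.41e-04 and 4.91e-05 for genotype and 0.927 and 0.112 for the crossed split. For replicate 2 against replicate 1 lines it was 0.461 and 0.0893. Genotype and differences between lines cannot be told apart here, with 2 lines per genotype, and a direct or indirect effect of Zac1 stays open and untested.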

How the results depend on the processing

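The fits with 16 or 12 libraries and the replicate block, and those of the 4 summed libraries of a genotype comparison alone, were chosen after seeing the data; the other alternatives were planned. Counts of genes stayed within 1.5 times in 91 of 130 alternatives. For Plagl1 in the summed libraries the direction held in each alternative run, and its call was lost in 1, at quiescence with the 4 summed libraries alone (log2 -1.90). Of the other values, 877 for named genes kept direction and call, 18 lost the call, 7 gained it and 1 changed sign without a call, and for single lists 313 kept the call, 148 lost it and 1 reversed. RLE and upper-quartile scaling moved the median of all genes by at most 0.07 on the log2 scale and changed the sign of no called list's median. Where the cause of a change below is not the smaller number of samples or the stricter test itself, the cause was not tested.

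With an estimated correlation, the called lists went from 15, 14 and 10 for genotype at quiescence, in proliferation and for the interaction to 0, 0 and 0, and from 18 and 20 for state in wildtype and mutant cells to 3 and 3. DESeq2 called 3 genes for genotype in proliferation, 1 for the interaction and 15 at day 10, and 306 and 357 for day 12 against day 8 in wildtype and mutant cells. Against a fold change of 1.5, the state counts were 3452 in wildtype and 2703 in mutant cells. Fits of only the 4 libraries compared gave 0 at quiescence, 0 at each of days 8, 10 and 12, and 23 and 0 for day 12 against day 8 in wildtype and mutant cells.

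For the genotype comparisons, a wildtype and a mutant line share a number and a letter, whose meaning is not given, so the lines were not paired. The deviations of same-numbered lines correlated with r = 0.01 at quiescence and -0.03 in proliferation across tested genes (Spearman 0.28 and 0.26), and with 0.29 and 0.36 over genes of at least 10 CPM (Spearman 0.49 and 0.56). Mutant minus wildtype in the I lines against the same in the L lines gave r = -0.34 at quiescence and -0.12 in proliferation (Spearman -0.06 and 0.02). With the pairing crossed, r was -0.36 and -0.09. Genotype differences across genes were thus not shared by the pairs. With the replicate block the counts were 1 at quiescence, 1 in proliferation, 1 at day 8, 2 at day 10 (Plagl1 and Nuak2) and 1 at day 12, with 16 and 15 lists called. With the line as a block, where the line is the pair, the interaction gave 0 genes and 12 lists, state 7472 and 6633 genes and 22 and 20 lists, and day 12 against day 8 304 and 319 genes. Counts of calls in these fits changed by more than 1.5 times only for day 12 against day 8 and for genotype at day 10 (1 without and 2 with the block). With repeat harvests taken as independent, the replicate block gave 7 genes at quiescence over 16 libraries (Plagl1, Cdkn1c, Gpc3, Nsg1, Nuak2, Comp and Cilp2) and 14 over the 12 quiescent libraries with day as a term.

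Leaving out 1 line, which leaves a lone line assumed to vary like the other groups, gave 1 to 4 genes for genotype at quiescence, 1 to 3 in proliferation, 0 to 2 at day 8, 0 to 51 at day 10 and 0 to 1 at day 12. It gave 4185 to 7755 for state in wildtype cells, and for day 12 against day 8 0 to 192 in wildtype and 29 to 74 in mutant cells. The called lists ran from 3 (without wildtype replicate 1, none of them lower) to 14 for genotype in proliferation and from 7 to 16 for the interaction. The cartilage marker list at quiescence had adjusted p from 3.56e-29 to 0.552 and reversed without mutant replicate 2 (adjusted p = 7.17e-07). Depth limits genes of low count. Whether the low counts of calls are set by sample size cannot be decided here. Simulated 2-fold changes were recovered for 73.1% of genes at quiescence, but the simulation planted many changed genes, which eases the adjusted threshold. It also drew genes as independent, and 12 of its 140 calls were false. The real quiescent comparison differed from it, with 76 genes at an unadjusted p under 0.05 against 787 by chance.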

Other observations

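The genes below were chosen after their values were seen. Single genes differed between cultures of one genotype. At quiescence the cartilage collagen gene Col11a2 stood at 27.6 CPM in mutant replicate 2 and at 5.85 or less in the other 3 lines. The hindlimb transcription factor gene Pitx1 stood at 5.72 CPM in wildtype replicate 1 and at 34.7, 34.8 and 25.3 in wildtype replicate 2 and mutant replicates 1 and 2, and Aqp5, a water channel, at 10.8 against 62.0, 60.9 and 53.5. The imprinted gene Mest differed between the replicate numbers, at 388 and 373 CPM in the replicate 1 lines and 690 and 759 in the replicate 2 lines (log2 0.93, SE 0.10, edgeR adjusted p = 0.00784 for replicate 2 minus replicate 1), while its genotype value was 0.07 (SE 0.39, edgeR adjusted p = 1.00).

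Other changes from proliferation to quiescence were shared by the genotypes. The epithelial keratins Krt19 and Krt18 fell, with Krt19 at log2 -2.76 (SE 0.14, edgeR adjusted p = 1.26e-06) in wildtype and -2.58 (SE 0.14) in mutant cells. The growth-promoting factor Myc fell by 1.88 and 1.59, and the cell cycle inhibitor Cdkn2a rose by 1.30 and 1.43 (SE 0.19 in each). The stress genes Trib3 and Ddit3 rose by 2.65 and 1.68 in wildtype and by 2.58 and 1.92 in mutant cells, in an endoplasmic reticulum stress list that went both ways (5 of 17 rose and 6 fell in wildtype, 5 and 5 in mutant cells) and was not called (camera adjusted p = 0.512 and 0.267). The cytoskeletal gene Actb, often used as a reference, fell by 1.21 and 1.04 (SE 0.11).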
